A study of Mus musculus with 3 samples.

How the data were processed

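5-Hydroxymethylcytosine (5hmC) was profiled in genomic DNA of mouse cerebellum in 3 sequencing libraries, with 1 library per group. Control cerebellum and cerebellum after chronic sleep deprivation were each profiled by DDD-seq, and cerebellum was also profiled by ACE-seq. The title of the DDD-seq control calls its tissue normal, whereas that of the ACE-seq library names mouse cerebellum only. The control status of the ACE-seq library is therefore inferred, and the name ACE-seq control is used here on that basis. The number of animals behind each library is not given in the sources used here. In DDD-seq (double-stranded DNA deamination sequencing), 5hmC is glycosylated and the DNA is then treated with the deaminase domain SsdAcat, per the labels' protocols. Cytosines that resist deamination are read as 5hmC. ACE-seq is an APOBEC-coupled method that also protects glycosylated 5hmC from a deaminase. The labels give the ACE-seq library the same protocol text as the DDD-seq libraries, SsdAcat included, so its own deamination step is not given in the sources used here.

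The deposited table holds a fraction for each library in consecutive bins of 10 kb, per the file headers and the range of the values. The fractions were multiplied by 100 and are given as levels in percent. Per the submitters' processing notes, FastQC, Trimmomatic and Bismark were used. The file headers carry words for trimming, Bismark, sorting and merging, and the word hapinfo, which is not explained. How the fraction was averaged, over which cytosine contexts, and with which coverage filter is not given in the sources used here. The headers of both DDD-seq columns carry the word "all", so runs or libraries may have been pooled in them. Both are treated as the authors' values for their group. The table gives no read counts and no coverage, so the depth behind each value is unknown, and no counting interval, detection limit or per-site test was possible. No unmodified control DNA was analysed here, so the levels include any cytosine left unconverted.

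The processing notes name hg19, a human build. The bins, however, cover mouse chromosomes 1 to 19, X and Y. On each of these 21 chromosomes the last bin ended between 1.33 and 211.9 kb after the end of the last gene in a RefSeq gene table of GRCm38.p6, and bins were therefore treated as GRCm38. A shift of the gene positions against the bins (below) was used as a second check. Coordinates are those of the bins, counted from 1. The gene table gives no strand and no exons, so promoters and exons were not analysed.

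The table lists 264399 bins, of which 262974 had a value in all 3 libraries. A bin was called genic when it overlapped a protein-coding gene by at least 1 bp. The gene-body level was the mean over the bins a gene overlaps, and its standard error (SE) was taken over those bins. Differences between libraries were taken bin by bin, and their SE is that of the mean paired difference. These errors measure the scatter between bins inside a gene, not between animals. With 1 library per group there is no replicate error, so no p-value is given and every comparison is one of libraries, not of conditions or of methods in general. Gene bodies can share bins with overlapping or nested genes. Intervals of genome-wide means came from drawing 1 Mb blocks of the genome with replacement (95% range; 1000 draws, or 300 for genic minus intergenic differences) and cover variation between regions of the genome.

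The chance level of gene-body differences was taken from 100 draws in which each bin's difference from its gene's mean was given a random sign, the same sign for every pair of libraries and for genes that share the bin. Gene lists for cerebellar cell types, other cell types that the tissue could hold, receptors, synapse, clock, stress, DNA methylation and other groups were fixed before the data were examined. The median level of a list was placed among 10000 random lists of the same size matched on the number of bins, and its median difference among lists matched on level and number of bins. Of 346 listed symbols, 341 matched a protein-coding gene, 4 were long noncoding RNAs and were left out, and 1 was not found. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The gene-body test was tested on simulated data, with known differences added to some of the 1092 genes after bin differences were given random signs. In the sleep-deprived against control comparison, 33.3% of 48 genes changed by 0.25 percentage points lay beyond 3 SE. The share was 89.4% of 47 genes changed by 0.5 points, 100% of 48 genes changed by 1 point, and 0.456% of unchanged genes. The same difference was added to every bin of a gene, so changes that vary between bins were not simulated.

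The design written before the data were examined assumed cytosine sites with counts. The table holds bins without counts, so the Fisher tests, the coverage minimums of 5, 10 and 20 reads, strand merging, exon, promoter and site-density alternatives were not run, and the site minimums for genes were applied to bins. By the rule fixed before the data were examined, named genes are the 10 largest positive and 10 largest negative gene-body differences in each comparison among genes of at least 20 bins, and the 2 highest members and the lowest member of each list, taken here among genes of at least 5 bins and by level in the control DDD-seq library. Outside that rule, and after the data were seen, the 10 highest and 10 lowest genes of at least 20 bins by level in that library were named too, and naming was restricted to protein-coding genes. With long noncoding RNAs included, 19 of the 20 named genes of each comparison stayed the same. Alternatives were autosomes only, medians in place of means, values of 0 left out, other thresholds and other minimums of bins, and bins wholly inside a gene. Some genes that this rule or the added choice would name are not reported here.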

Results

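The data comprised 1 deposited 5hmC level per 10 kb bin of the mouse genome for each of 3 cerebellum libraries. These were DDD-seq of a control, DDD-seq under chronic sleep deprivation, and ACE-seq of tissue taken to be a control. The mean level over bins was 1.54% in the DDD-seq control (95% range over 1 Mb blocks 1.52 to 1.55), 1.55% in the sleep-deprived library (1.53 to 1.56) and 1.50% in the ACE-seq control (1.48 to 1.51). The distributions were right-skewed in all 3 libraries, with medians of 1.36%, 1.36% and 1.33% in the same order and 99th percentiles of 5.10%, 5.07% and 5.03%. A value of 0 was listed for 3.20% of bins in the DDD-seq control, 2.62% in the sleep-deprived library and 3.29% in the ACE-seq control. Bins without any value numbered 813, 537 and 675.

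The deposited 5hmC level was higher over genes than between them. In the DDD-seq control, bins that overlapped a protein-coding gene had a mean level of 1.76% against 1.35% for intergenic bins, a ratio of 1.31 and a difference of 0.413 percentage points (95% range over blocks 0.389 to 0.440). The corresponding difference was 0.392 points in the sleep-deprived library and 0.400 points in the ACE-seq control. Genic bins made up 44.7% of all bins, but 80.4% of the 2630 bins in the top 1% of the DDD-seq control. The top 1% of bins was shared to a large degree between libraries. A total of 1096 bins were in the top 1% of all 3 libraries, and 95.9% of these were genic.

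Gene bodies differed widely in level. Among 1092 protein-coding genes of at least 20 bins, the median in the DDD-seq control was 1.74%, and the 5th and 95th percentiles were 1.23% and 3.56%. The 10 highest and 10 lowest of them are named here by a choice made after the values were seen. The highest level was that of Cnksr2, a synaptic scaffold gene on chromosome X (bins 157820001 to 158050000), with 7.76% ± 0.68 (SE over 23 bins). Gabrb2, which encodes the beta2 subunit of the GABA-A receptor, followed with 6.26% ± 0.55 (chromosome 11, bins 42410001 to 42640000). Further genes were Brinp1 with 5.86%, the olfactomedin gene Olfm3 with 5.68%, Ppp3ca, encoding a catalytic subunit of calcineurin, with 5.46%, and Kcnd2, encoding an A-type potassium channel, with 5.36%. Fut8, a fucosyltransferase gene, had 5.20%, Zfpm2 5.04%, and Kctd8, an auxiliary GABA-B receptor subunit, 5.03%. The signal was bounded by the gene: in the 100 kb on either side, Cnksr2 had a flanking level of 1.59% and Gabrb2 1.87%. Across all 10 genes the flanking level in the DDD-seq control ranged from 1.51% at Brinp1 to 2.44% at Ppp3ca.

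The 10 lowest genes of at least 20 bins had levels between 0.83% and 1.06% in the DDD-seq control. They included Rp1, a photoreceptor gene, with 0.97% ± 0.09 (SE over 30 bins), the cytochrome P450 gene Cyp2c39 with 0.98%, the immunoglobulin-superfamily genes Skint5 with 0.95% and Skint6 with 0.97%, Zfp978 with 1.04%, and Prkdc, encoding the catalytic subunit of DNA-dependent protein kinase, with 1.06%. The remaining 4 were predicted genes, Gm21154 with 0.83%, Gm40847 with 0.95%, Gm40862 with 1.0% and Gm26650 with 1.02%. Several of these belong to families of similar copies, whose reads may be divided between copies, and their values are uncertain for that reason.

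**Figure D1:**
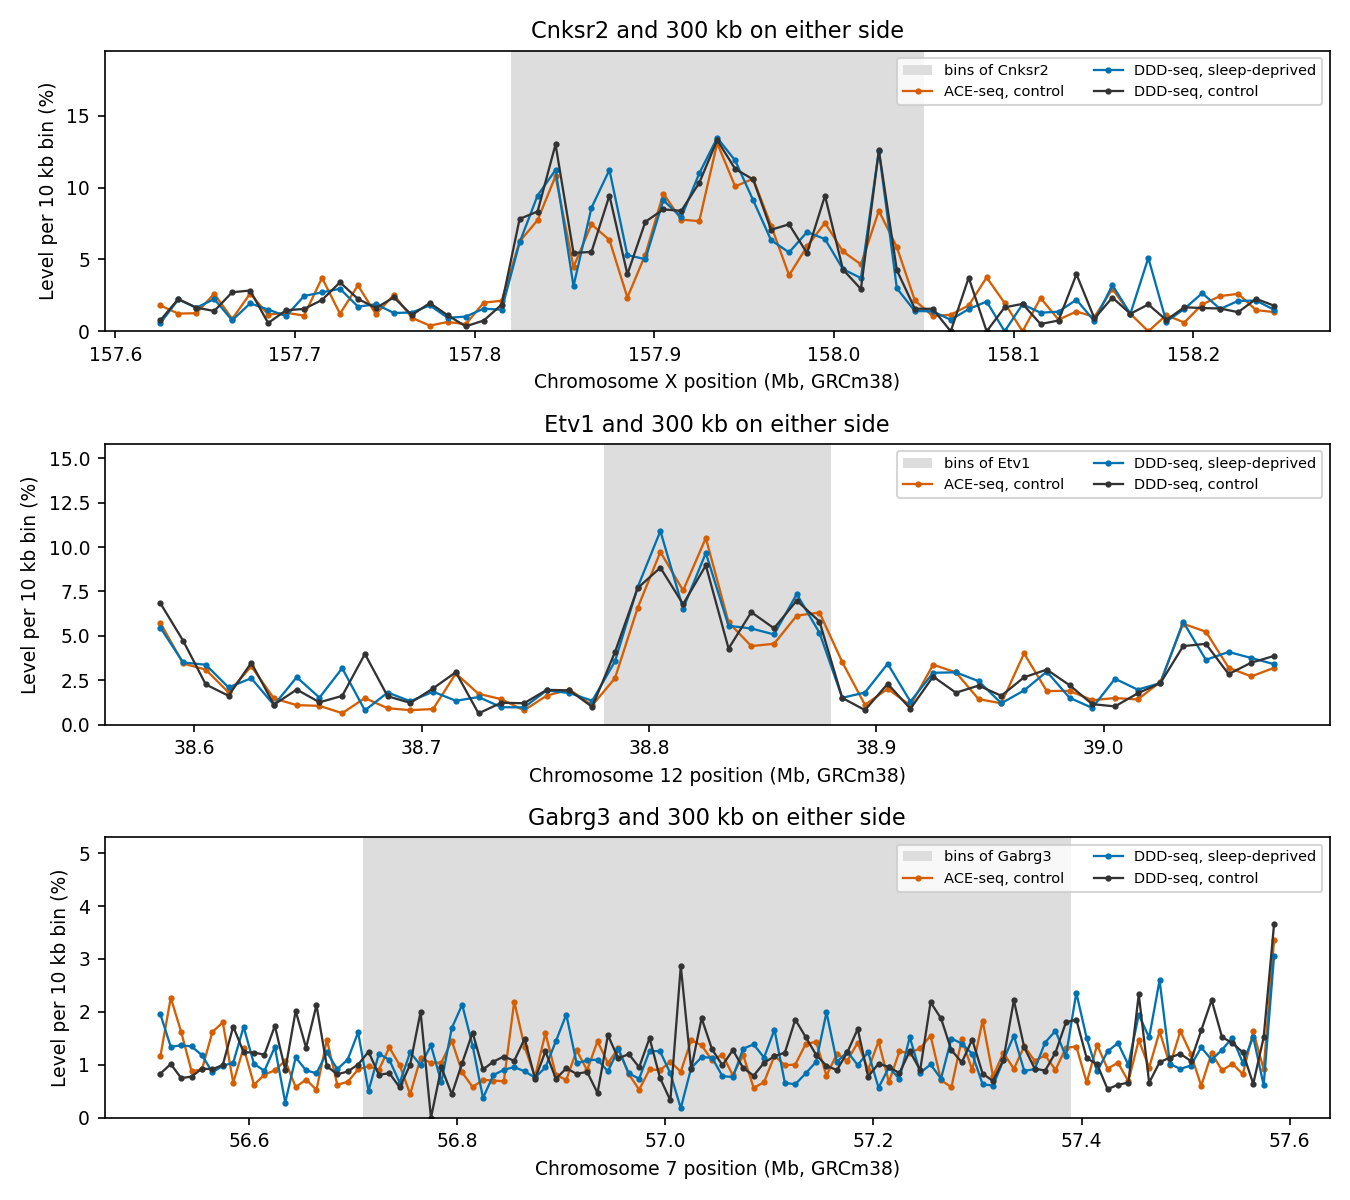
Deposited 5hmC level (percent, vertical axis) of each 10 kb bin against chromosome position (Mb) around Cnksr2, Etv1 and Gabrg3, with 1 line per library and the bins of the gene shaded; there are no error bars because each point is 1 value. The 3 libraries followed the same rise over Cnksr2 (7.0% to 7.76%) and Etv1 (6.42% to 6.70%) and stayed between 1.07% and 1.15% on average over Gabrg3. The panel titles give a wider span than the bins shown, which at Cnksr2 run from position 157620001 to 158250000.

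The level of gene groups was examined over genes of at least 5 bins, where the median of 6665 protein-coding genes was 1.54% in the DDD-seq control. Of the lists, that of granule cell genes had the highest percentile in each library. Its median over 7 genes was 3.06% in the DDD-seq control, 3.10% in the sleep-deprived library and 2.96% in the ACE-seq control, above at least 99.83% of matched random lists in each library. Over all 18 genes of any length, the medians were 1.62%, 1.57% and 1.66%, at percentiles 98.0, 96.15 and 99.3, so that in the sleep-deprived library this longer list lay inside the central 95%. Etv1, a transcription factor gene of granule cells, had 6.52% ± 0.54 (SE over 10 bins) and Kcnd2 5.36% ± 0.24, whereas Grm4, encoding a metabotropic glutamate receptor, had 1.59% ± 0.09. Genes of synaptic adhesion and scaffolds had a median of 2.26% over 16 genes, above 98.8% of random lists in the DDD-seq control. Among its members, Dlg1 had 3.67%, and Shank1, a postsynaptic scaffold gene, was the lowest with 1.22%. Genes of DNA methylation and demethylation enzymes had a median of 1.98% over 10 genes, at percentile 97.7 of random lists in the DDD-seq control, 98.6 in the sleep-deprived library and 96.0 in the ACE-seq control, with Uhrf2 at 3.30% ± 1.04 and the maintenance methyltransferase gene Dnmt1 at 1.18% ± 0.11. The stress and chaperone list had a median of 3.11% (percentile 98.9 in the DDD-seq control, 97.2 in the sleep-deprived library and 98.6 in the ACE-seq control) over only 3 measured genes: Nr3c1, the glucocorticoid receptor gene, with 3.99%, Sgk1 with 3.11% and Fkbp5 with 1.34%.

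Of the lists of other cell types, none with at least 3 measured genes lay above the central 95% of random lists in the DDD-seq control. Endothelial genes had a median of 1.24% over 8 genes, at percentile 1.57 in the DDD-seq control and 0.74 in the sleep-deprived library but 9.97 in the ACE-seq control, with Emcn at 2.83%, Vwf at 1.36% and Tek, an angiopoietin receptor gene, at 1.11%. Purkinje cell genes had a median of 1.57% over 11 genes (percentile 24.0). Plcb4, with 3.25%, was their highest member, and Car8, a carbonic anhydrase-related gene, was the lowest with 0.87%. Interneuron genes had a median of 1.44% over 8 genes (percentile 14.7), among them Ptprk with 2.35%, Nxph1 with 2.05% and Gad2, a GABA-synthesising enzyme gene, with 1.0%. The oligodendrocyte list had a median of 1.39% over 5 genes (percentile 24.0), with St18 at 2.41%, the myelin basic protein gene Mbp at 1.64% and Ugt8a at 1.09%. The median was 1.56% over 3 genes of Bergmann glia and astrocytes (percentile 57.5), where the glutamate transporter genes Slc1a2 and Slc1a3 had 1.85% and 1.56% and Aldh1l1 1.27%. It was 1.95% over 4 genes of unipolar brush cells (percentile 67.5), where Plcb1 had 2.33% and Lmx1a 1.30%. At most 2 genes of 5 bins were measured for microglia (P2ry12 1.73%, Itgam 1.54%), choroid plexus and ependyma (Clic6 1.13%, Kl 1.1%), blood (Ptprc 1.58%), the homeobox clusters (Hoxa3 1.15%, Hoxb3 0.93%), genes of other tissues (Apob 1.23%) and housekeeping genes (Hprt 2.51%), and these lists were not ranked.

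Among the remaining lists, GABA receptor genes had a median of 1.93% over 12 genes (percentile 91.0) and spanned the range from Gabrb2 with 6.26% to Gabrg3 with 1.15% over 68 bins. Glutamate receptor genes had a median of 1.58% over 20 genes (percentile 14.7) and ranged from Grik2 with 5.02% and Gria4 with 4.38% to Grin2d with 1.11%. Hereditary ataxia genes had a median of 1.98% over 12 genes (percentile 94.8), with Fgf14 at 4.55%, Atxn10 at 2.84% and Aptx at 1.13%. Circadian clock genes had a median of 1.58% over 11 genes (percentile 63.5), with the repressor gene Cry1 at 3.02%, Rora at 2.51% and Per2 at 1.25%. Immediate early genes had a median of 2.16% over 3 genes (percentile 94.8), which were Homer1 with 3.27%, Bdnf with 2.16% and Nr4a3 with 1.32%. Imprinted genes had a median of 1.58% over 8 genes (percentile 57.4), with Ube3a at 5.49%, Igf2r at 1.74% and Impact at 1.20%, and inflammation genes a median of 1.54% over 3 genes (percentile 51.0), with Nfkb1 at 1.75%, Stat3 at 1.54% and Il1r1 at 1.41%. With 17 ranked lists, 0.85 lists outside the central 95% are given by chance. With genes of at least 20 bins, 8 lists could be ranked and the granule cell list alone lay above the central 95% in the DDD-seq control; the DNA methylation, stress and endothelial lists had no gene of that size. With genes of at least 1 bin, the lists above it in the DDD-seq control were the granule cell, circadian clock and housekeeping lists (percentiles 98.0, 98.1 and 99.5). The stress and chaperone list then had a median of 1.35% over 14 genes (percentile 71.6), the DNA methylation list 1.4% over 21 genes (percentile 61.4) and the synaptic list 1.83% over 19 genes (percentile 90.6), all inside the central 95%.

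**Figure D2:**
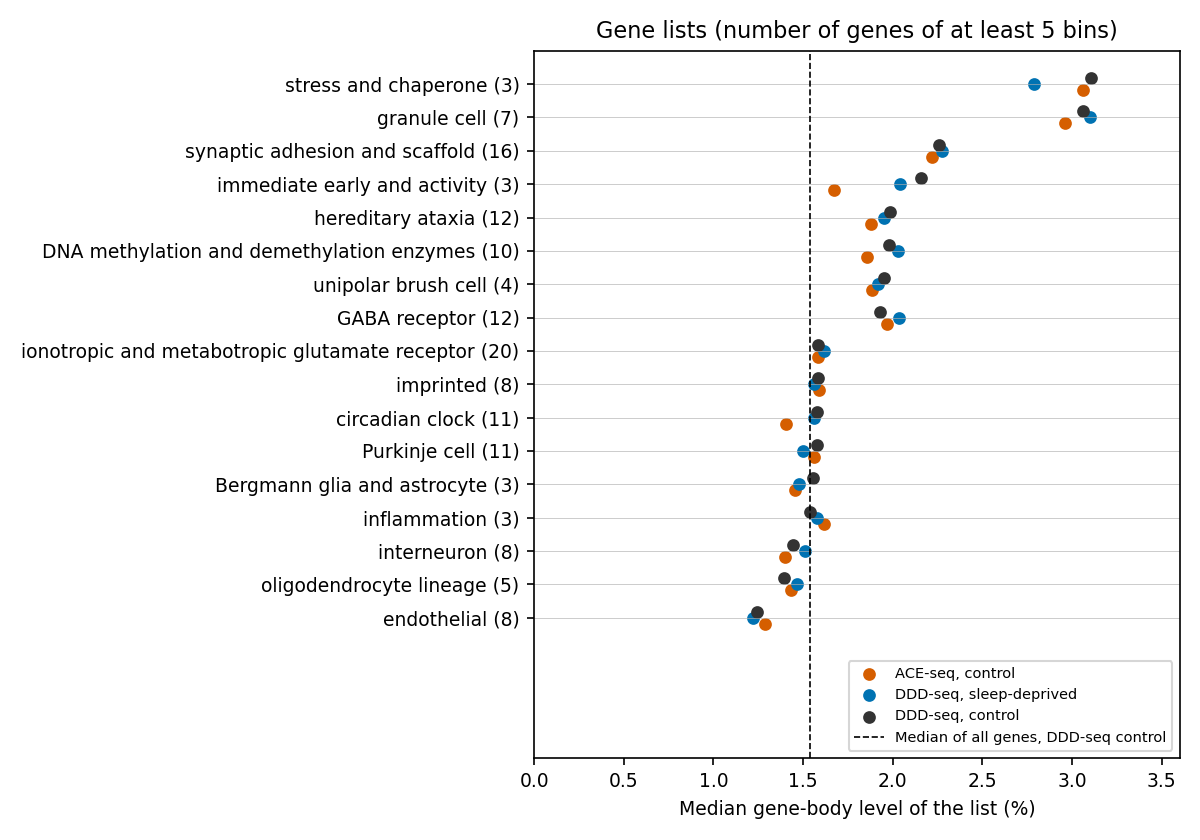
Median gene-body 5hmC level (percent, horizontal axis) of each gene list with at least 3 measured genes (number in parentheses), with 1 point per library and the median of all genes in the DDD-seq control as a dashed line. The granule cell list lay at 2.96% to 3.10% in the 3 libraries and the endothelial list at 1.22% to 1.29%.

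The first comparison asked how the DDD-seq control compares with the ACE-seq library, which was taken as a control without its title saying so. Gene-body levels were closely correlated: across the 1092 genes of at least 20 bins, Pearson's r was 0.988 and Spearman's rho 0.971 (genes are not independent replicates). The same genes were high by both methods, as in Cnksr2 (7.0% by ACE-seq, 7.76% by DDD-seq) and Brinp1 (5.86% by both). Of the 1092 genes, 93 exceeded 3% in all 3 libraries. ACE-seq levels were slightly lower: the ACE-seq minus DDD-seq difference had a median of -0.0526 points over genes (766 lower, 326 higher) and a mean of -0.0393 points over bins (95% range over blocks -0.0440 to -0.0346).

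The ACE-seq minus DDD-seq difference was -0.77 ± 0.37 points (SE over bins) at Cnksr2, -0.53 ± 0.25 at the angiopoietin gene Angpt1, -0.51 ± 0.34 at Kctd8, -0.46 ± 0.19 at the cell adhesion gene Chl1, -0.46 ± 0.27 at Cdc42bpa and -0.45 ± 0.12 at Atp9b. It lay between -0.42 and -0.35 points at 6030498E09Rik, Pola1, Hs6st2 and Tmem178b. ACE-seq was higher by 0.68 ± 0.41 points at Gabrb2, 0.57 ± 0.21 at Phf14, 0.53 ± 0.31 at Olfm3, 0.52 ± 0.26 at the neuronal membrane glycoprotein gene Gpm6a and 0.41 ± 0.20 at Tenm1. It was higher by 0.31 to 0.39 points at Nhs, Oxr1, Tll1 and Plekhg1. A total of 11 genes differed by more than 3 SE, all lower by ACE-seq, against 1 to 13 genes in 100 draws with random signs. The draws hold no offset between libraries, and the offset was not removed from the observed differences. The count of 11 therefore includes the effect of the offset, so count and range are not like for like. The draws also do not bear on the genes all being lower. In 24 of the draws, the largest difference at any of the 1092 genes was as large as that at Cnksr2, which also carries the offset. Of the 17 ranked gene lists, 1 lay outside the central 95% of matched random lists for this difference, that of glutamate receptor genes (median 0.0102 points, percentile 97.6), where 0.85 are given by chance. This list lay inside the central 95% with genes of at least 20 bins (median -0.00928 points, percentile 91.8) and of at least 1 bin (percentile 94.95).

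Single bins agreed less than genes. Across bins, Spearman's rho between DDD-seq and ACE-seq controls was 0.479 and Pearson's r 0.418, and with autosomes only r was 0.628. On autosomes rho rose with the window, from 0.490 at 10 kb to 0.813 at 100 kb and 0.953 at 1000 kb. A difference of at least 20 points was seen in 76 bins, of which 63 were on chromosome Y, 5 on X and 8 on autosomes. Among bins with a value in all 3 libraries, the 10 highest in the DDD-seq control, at 50 to 100%, were on chromosomes 14, X and Y, and the ACE-seq control listed 0 in each of these 10. The sleep-deprived DDD-seq library also listed 0 in 8 of them, and these bins were picked for their value in the DDD-seq control.

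**Figure D3:**
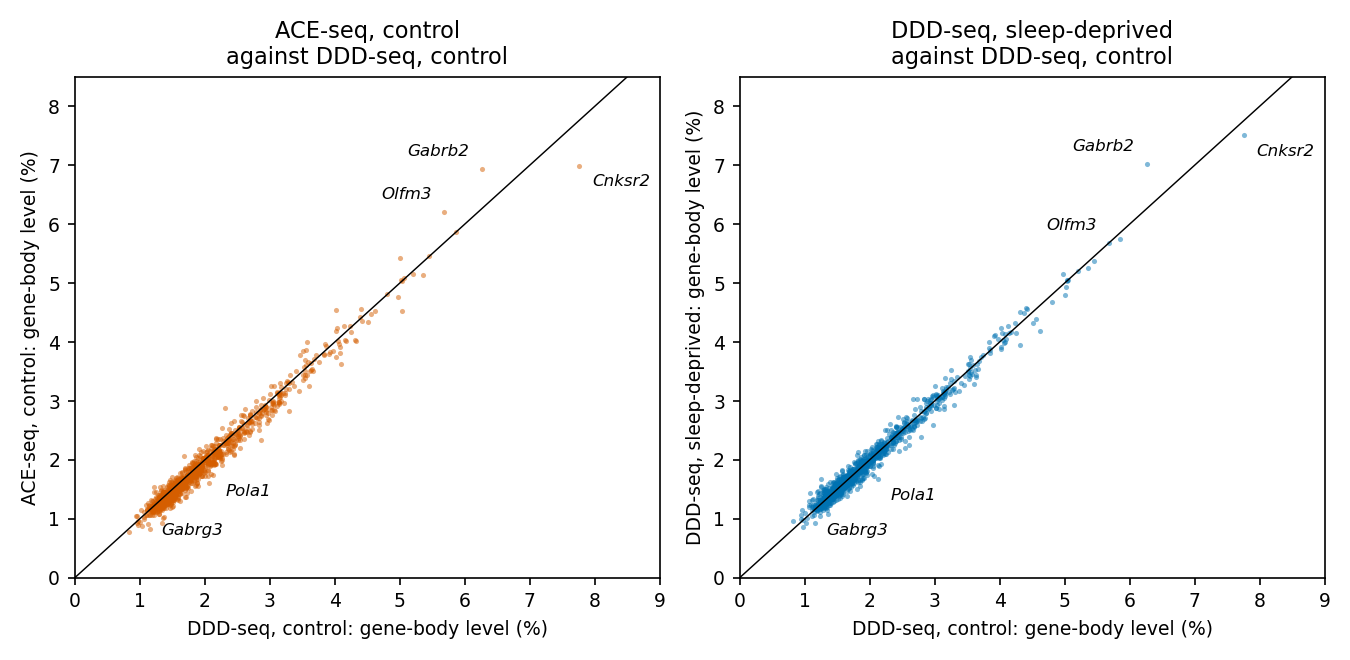
Mean gene-body 5hmC level (percent) of 1092 protein-coding genes of at least 20 bins in the ACE-seq control (left) and the sleep-deprived DDD-seq library (right) against the DDD-seq control, with 1 point per gene and the line of equal levels. Points lie along the line in both panels (Pearson's r 0.988 and 0.991), with Cnksr2 and Gabrb2 at the upper end.

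The second comparison set the sleep-deprived DDD-seq library against the DDD-seq control. The gene-body profile was nearly the same: Pearson's r across the 1092 genes was 0.991 and Spearman's rho 0.975. The median difference over genes was -9.5e-05 points, with 545 genes higher and 547 lower in the sleep-deprived library, and the central 95% of genes lay between -0.217 and 0.212 points. Of these genes, 1 difference, at Gabrb2, exceeded 0.5 points. Over bins the sleep-deprived library was higher by a mean of 0.00760 points (95% range over blocks 0.00366 to 0.0114). This mean turned to -0.000544 points when values of 0, which were fewer in the sleep-deprived library, were left out.

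The gene with the largest difference was Gabrb2, with 7.03% in the sleep-deprived library and 6.26% in the control (0.76 ± 0.37 points higher, SE over 23 bins); the ACE-seq control was also higher than the DDD-seq control there, with 6.94%. The other genes at the upper end were Ccdc85a (0.42 ± 0.16 points higher), the Akt phosphatase gene Phlpp1 (0.38 ± 0.15), the coagulation factor genes F8 (0.35 ± 0.18) and F13a1 (0.31 ± 0.13), the bicarbonate transporter gene Slc4a10 (0.31 ± 0.16), Bank1 (0.31 ± 0.13), Phf14 (0.29 ± 0.22), the integrin gene Itga8 (0.29 ± 0.14) and Itgbl1 (0.28 ± 0.14). At the lower end, the sleep-deprived minus control difference was -0.45 ± 0.17 points at Pola1, a DNA polymerase alpha gene (1.67% against 2.12%), and -0.43 ± 0.15 at the netrin receptor gene Unc5c (4.19% against 4.63%). It was -0.40 ± 0.30 at the glycine receptor gene Glra2, -0.39 ± 0.25 at Fgd4, -0.37 ± 0.18 at Cdc42bpa, -0.35 ± 0.16 at the ephrin receptor gene Epha3 and -0.35 ± 0.20 at Zfp804a. It was -0.34 ± 0.14 at Csrnp3, -0.33 ± 0.15 at Atp9b and -0.32 ± 0.22 at Ptchd4.

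The number of genes beyond 3 SE and the size of the largest difference did not exceed those given by scatter between bins. A total of 4 genes differed by more than 3 SE, Tnr and Ksr2 higher and Zfp469 and Pebp4 lower in the sleep-deprived library, against 2 to 14 genes in 100 draws with random signs. Their differences were 0.23 ± 0.07 points at Tnr, 0.17 ± 0.05 at Ksr2, -0.19 ± 0.04 at Zfp469 and -0.12 ± 0.04 at Pebp4. These 4 are named outside the rule for named genes, after their values were seen. Only Zfp469 lay beyond 4 SE, and the draws were not counted at that bound, so they do not decide this gene. In 18 of the 100 draws, the largest difference at any of the 1092 genes was as large as that at Gabrb2. How often Gabrb2 itself reached it was not counted. On simulated data with an even change over each gene, 89.4% of 47 genes changed by 0.5 points passed the 3 SE bound in this comparison. The share was 33.3% of 48 genes changed by 0.25 points. These shares are over genes of all levels and were not computed for the highest genes alone, several of which had a large SE of the difference: 0.37 points at Gabrb2, 0.37 at Fut8, 0.33 at Kctd8 and 0.32 at Cnksr2.

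None of the 17 ranked gene lists differed between the sleep-deprived and the control library beyond the central 95% of random lists matched on level and size. Circadian clock genes had a median difference of -0.0180 points, with 4 higher and 7 lower (percentile 36.6). Rora differed by 0.02 ± 0.06 points, Cry1 by -0.02 ± 0.09 and Per2 by -0.10 ± 0.10. Stress and chaperone genes differed by a median of -0.00754 points (percentile 62.7) and immediate early genes by -0.119 points (percentile 19.3), each over 3 genes. Genes of DNA methylation and demethylation enzymes differed by -0.0462 points (percentile 37.3). The granule cell list differed by 0.0373 points (percentile 78.4). The largest percentile was that of glutamate receptor genes, with a median difference of 0.0519 points and 14 of 20 genes higher (percentile 97.3). The same list lay outside the central 95% for the ACE-seq minus DDD-seq difference. Both differences subtract the same DDD-seq control, so they are not separate observations.

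**Figure D4:**
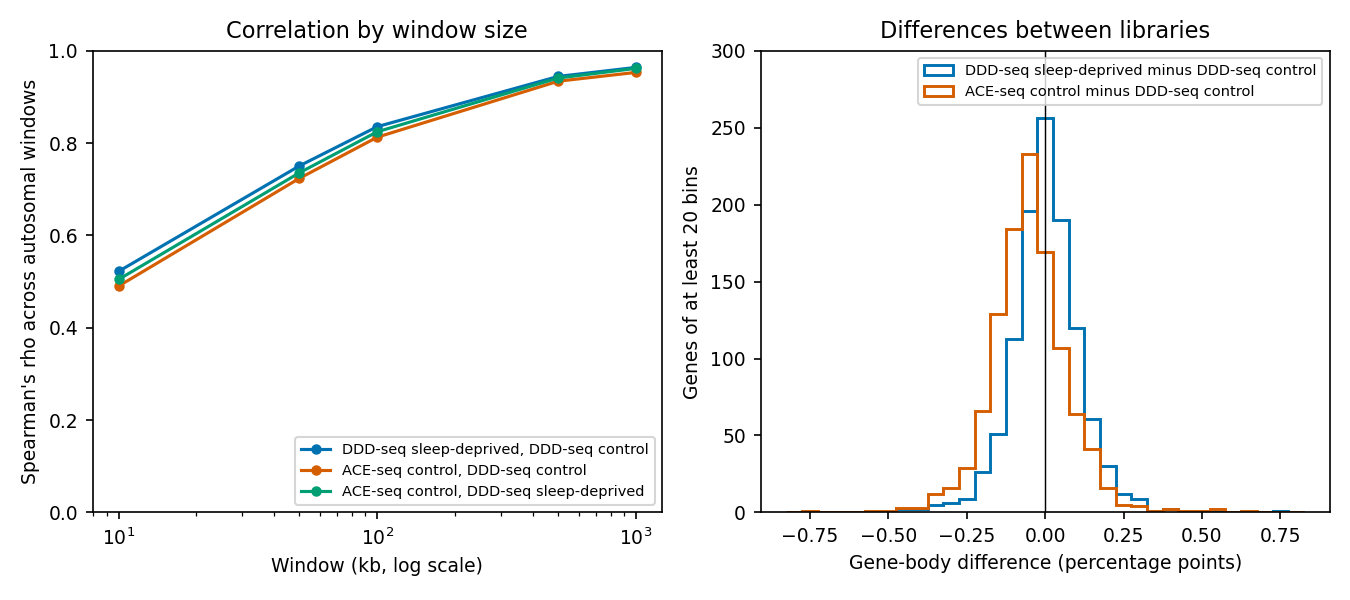
Left, Spearman's rho between libraries across autosomal windows against window size (kb, log scale), with 1 line per pair; right, number of genes of at least 20 bins by gene-body difference from the DDD-seq control (percentage points). Spearman's correlation rose from 0.490 to 0.522 at 10 kb to 0.953 to 0.964 at 1000 kb, and the ACE-seq differences had a median of -0.0526 points.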

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

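Each group had 1 library, so leaving out a replicate is not possible and no alternative gives a replicate error; a value is called moved here when it left the 95% range over blocks or over resampled genes. No paired analysis was possible because each group has 1 library. Coverage minimums, strand merging, exons, promoters, site density and region scores could not be run on bins without counts, and overlap of sites has no meaning for bins listed in all libraries. The depth is unknown, so the precision of single bins cannot be given. Settings for bins wholly inside genes, long noncoding RNAs, the top 1% of values, genes of at least 5 bins (1 bin for lists) and other SE bounds were chosen after seeing the data.

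In the order ACE-seq control, sleep-deprived and DDD-seq control, mean levels were 1.52%, 1.57% and 1.56% on autosomes and 1.55%, 1.59% and 1.59% without values of 0. They were 1.44%, 1.48% and 1.48% without the highest 1% of values, and 1.33%, 1.36% and 1.36% as medians. All of these levels had moved. The genic minus intergenic difference stayed positive, at 0.372, 0.361 and 0.376 points on autosomes and 0.376, 0.373 and 0.380 without values of 0. It was 0.222, 0.201 and 0.222 as medians, and 0.358, 0.354 and 0.374 with long noncoding RNA genes counted as genic. All of these differences had moved except that of the sleep-deprived library without values of 0. The X minus autosome difference in mean level was -0.0746, -0.0900 and -0.0906 points and turned to 0.0762, 0.00565 and 0.0675 without values of 0, of which X held more.

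The sleep-deprived minus control mean over bins turned from 0.00760 to -0.000544 points without values of 0, and its median was 0. The ACE-seq minus DDD-seq mean was -0.0448 points on autosomes and -0.0303 as a median. Pearson's r over bins rose to 0.690 (sleep-deprived) and 0.628 (ACE-seq) on autosomes and to 0.735 and 0.705 without values of 0, and Spearman's rho on autosomes was 0.522 and 0.490. Bins at least 20 points apart numbered 74 (sleep-deprived) and 76 (ACE-seq). These became 226 and 246 at 10 points, 29 and 38 at 30 points, 7 and 8 on autosomes, and 1 and 0 without values of 0.

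Over genes, autosomes, values of 0 left out and bins wholly inside genes left r and the median difference within these ranges in both comparisons. The number of genes beyond 3 SE has no such range and stayed at 4 (sleep-deprived) and 11 (ACE-seq). With genes of at least 5 bins, r was 0.952 and 0.953 and the ACE-seq median difference -0.0457. Beyond 3 SE lay 117 and 139 genes, against 110 to 161 and 112 to 162 in draws with random signs. The ACE-seq count of 139 includes the effect of the offset between libraries, which the draws lack. Among genes of at least 20 bins, 59 and 105 lay beyond 2 SE, and 1 (Zfp469) and 0 beyond 4 SE. Of gene lists, 4 lay above the central 95% of random lists in the DDD-seq control with 5 bins, 1 with 20 bins and 3 with 1 bin. Below it there was 1 with 5 bins, 0 with 20 and 3 with 1 bin. These 3 were the endothelial, homeobox and oligodendrocyte lists (percentiles 0.23, 1.07 and 1.25). In the sleep-deprived library and the ACE-seq control the oligodendrocyte list lay at percentiles 10.79 and 18.21, inside the central 95%. For the sleep-deprived minus control difference, 1 list, inflammation, lay outside the central 95% with genes of at least 1 bin (median -0.161 points, percentile 2.32), where 1.15 of 23 lists are given by chance. For the ACE-seq minus DDD-seq difference, 1 list lay outside it with 5 bins (glutamate receptors), 0 with 20 bins and 1 with 1 bin (Bergmann glia and astrocytes, median -0.267 points, percentile 0.41). The cause was not tested for any of these shifts except where the setting itself leaves out bins, genes or members.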

Other observations

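The tests of one library's artefact and of a uniform offset, the gene families and the receptor genes below were chosen after the values had been seen; the other tests were set out before their results were known. GABA-A receptor subunit genes differed widely in the DDD-seq control. On chromosome 11, Gabrb2 had 6.26% ± 0.55 (SE over bins) and Gabra6, the subunit typical of granule cells, 2.99% ± 0.26. On chromosome 7, Gabra5 and Gabrg3 had 1.4% ± 0.18 and 1.15% ± 0.06. The chromosome 5 genes had 1.99% ± 0.19 at Gabra2, 1.86% ± 0.10 at Gabrb1, 1.76% ± 0.24 at Gabra4 and 1.26% ± 0.19 at Gabrg1. The demethylating dioxygenase genes had 1.51% ± 0.13 at Tet1, 1.97% ± 0.20 at Tet2 and 2.13% ± 0.20 at Tet3.

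Gene families were described by their medians, without a test against random lists. In the DDD-seq control, the median over genes of any length was 1.06% for 1107 olfactory receptor genes, 0.98% for 339 vomeronasal receptor genes, 1.04% for 99 cytochrome P450 genes and 1.02% for 71 defensin genes, against 1.33% for all 21676 protein-coding genes. The homeobox list had 1.04% over 18 genes of any length (percentile 1.07 among matched random lists). A short gene's bins include flanking sequence, and families of similar copies can share reads. Of other families examined, keratin genes had a median of 1.17%, ribosomal protein genes 1.25%, collagen genes 1.28%, potassium channel genes 1.34%, zinc finger protein genes 1.36%, cadherin genes 1.44%, teneurin genes 1.73% over 4 genes and contactin genes 1.96% over 6 genes. Axonemal dynein heavy chain genes, which are long, had a median of 1.23% over 15 genes, against 1.54% for all genes of at least 5 bins. Chromosome 7 had the lowest median of the autosomes, 1.25% in the DDD-seq control, and chromosome 16 the highest, 1.47%. On chromosome Y, 64.3% of bins with a value were listed at 0 in the DDD-seq control.

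The first pattern is the high level over the bodies of certain genes. An artefact of one library is argued against by the rank agreement of genes, with a lowest Spearman's rho of 0.971 among the 3 pairs of libraries. Misplaced gene coordinates are argued against as well: the level over genes of at least 20 bins exceeded that of their 100 kb flanks by 0.466 ± 0.023 points (SE over 1092 genes), and after a shift by 200 kb the contrast was -0.136 times as large. Measured against intergenic bins in the DDD-seq control, the excess was also largest unshifted, at 0.629 points. More of it stayed there, 0.361 and 0.372 points after shifts by 200 kb to either side. After shifts by 1000 kb it was still 0.246 and 0.239 points, so part of this excess was not particular to the gene positions. Gene length alone gives little of the order of these genes, since rho between level and number of bins was 0.129; it was higher, at 0.277, among genes of at least 5 bins. Sequence composition, local CpG density and incomplete deamination that all 3 libraries share could not be tested without a genome or unmodified DNA, and remain open beside a difference in 5hmC itself.

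The second pattern is the set of gene-body differences between the sleep-deprived and control DDD-seq libraries. Scatter between bins may account for the number of genes beyond 3 SE, which was 4 where draws with random signs gave 2 to 14. This count does not decide single genes. If chronic sleep deprivation were behind the 20 named differences, the ACE-seq control would lie near the DDD-seq control at those genes. The median offset of -0.0526 points was removed first. The median position of the ACE-seq control was then 0.582, on a scale from 0 at the DDD-seq control to 1 at the sleep-deprived library. Random draws without gene-body effects gave a median of 0.586 and a central 95% of 0.368 to 0.824. The 20 genes were picked for their difference from the same DDD-seq control, and the ACE-seq control is 1 library by another method. The position therefore does not decide whether sleep deprivation is behind these differences. An effect of sleep deprivation at these genes, smaller effects, effects in short genes and effects in few cells stay open with 1 library per condition.

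The third pattern is the lower level by ACE-seq. A uniform offset over all bins is argued against: the ACE-seq minus control difference was -0.0464 points in genic and -0.0336 in intergenic bins, -0.0128 apart (95% range over blocks -0.0237 to -0.00347), where a proportional loss gives -0.0106. On autosomes alone these were -0.00349 apart (-0.0100 to 0.00245). This range includes the value of 0 that a uniform offset gives and only narrowly leaves out the -0.0108 of a proportional loss. Over gene bodies the slope of the difference on the level in the sleep-deprived library was 0.00369 (95% range over resampled genes -0.0158 to 0.0236), where a proportional loss gives -0.0256. The mean difference was -0.0448 points on autosomes, -0.0206 on X (-0.0486 to 0.00455) and 0.0947 on Y (-0.0281 to 0.216). The form of the difference over the whole genome and the step that gives it stay open, and method and library cannot be separated with 1 library each.

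Both comparisons share the DDD-seq control. Their gene differences correlated at 0.459, and draws with random signs gave 0.445 to 0.573; the covariance was 0.00621 against a mean of 0.00752 in the draws. The 2 lists of named genes had 5 in common, Gabrb2, Phf14, Pola1, Cdc42bpa and Atp9b. The shared control cannot be split, since it is 1 library. The correlation lies within draws that hold no gene-body effect. Those draws keep the covariance of the bin differences whatever its source, so they do not single out the shared control.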
